A study of Mus musculus with 1545 samples.

How the data were processed

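Neurons of the spinal cord dorsal horn of mice were dissociated and sequenced as single cells, and each of the 1545 samples of the series is 1 cell. Per the labels' protocols, grey matter of the dorsal horn was taken from young mice, digested with papain and TrypLE, triturated, strained and cleared on a density gradient before capture. The protocol text goes on with wording of a droplet kit, while the titles of the cells give a capture run and a well, and the deposited table is named as C1 data, a chip with wells. The run-and-well labels were used here. How fluorescent cells of the reporter lines were picked is not given in the sources used here, nor is how doublets or weak cells were removed. The labels give each cell's line, age in days, sex, total of molecules, cluster name and cell type.

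The deposited table holds molecule (UMI) counts per gene and cell, not normalized, per the labels, which name molecule counts and a total for each cell. The submitters' processing notes name Cell Ranger and the genome build mm10, and other steps and the versions are not given in the sources used here. The sum over genes equalled the deposited total of molecules in all 1545 cells. The table has 24378 genes below 6 lines of annotation, of which 4507 have no count in any cell. Symbols ending in _loc and a number, 1207 in all with 0.3765% of counts, stand for genes with several genomic copies, and their counts are uncertain. Rims1, Scn2a and the reporter transgenes have no entry of that name and were not analysed here. No cell was removed.

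The median cell held 8808 UMIs (3012 to 32886) and all cells together 14853604 UMIs from 82 capture runs, with 6442953 in wild type (67 runs, ages 18 to 28 days), 5730737 in the vGat line (8 runs, 17 to 24 days) and 2679914 in the vGlut2 line (7 runs, 23 to 26 days). Medians of 3137, 3953 and 3045 genes were seen per cell. Intervals and floors cover counting error only, with a floor of 3 counts over a group standing for a count of 0.

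Cells were grouped by line, and summed counts per animal set (line, sex label and age label) were the unit of every test. Cells of different age labels cannot come from the same mouse, while the pair of 22-day wild-type sets, parted by the sex label alone, may share mice. No capture run held more than 1 line or more than 1 animal set (0 runs), so line and run cannot be told apart in comparisons between lines, that of the reporter lines included. Types and classes were taken from the authors' annotation, with the 18 cells whose labels disagree kept apart from both classes. The animal set was a block where both arms came from the same sets (classes in wild type, neuron types, conflicting type), since these share mice.

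Comparisons used edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test, TMM factors, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05. The reporter lines were compared over all their cells, and the other comparisons over sets with at least 10 cells of the class, where set totals ran from 104520 to 2610600 UMIs. Neuron types were fitted on sums of at least 2 cells per set and type, each type against the mean of the other types of its class. Those tests were adjusted over list genes and types together, and genes in a type's own name were left out. Age trends were slopes per day in wild-type sets labelled male. Differences between class effects in the reporter lines and in wild type, and between age slopes of the classes, were tested as interaction terms. The term for class effects took inhibitory cells of the vGat line and excitatory cells of the vGlut2 line, without the animal set as a block. Type shares were compared with exact two-sided permutation tests over sets. Shares of cells with a UMI were computed after thinning each cell to 3000 UMIs, with exact binomial 95% intervals. CPM are UMI counts scaled so that each set's total is 1000000.

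Gene lists were 16 lists of neuronal functions, 9 lists of markers of other cells, and the ribosomal protein and mitochondrially encoded genes (2 lists). They were tested with camera (preset correlation 0.01, and an estimated correlation) and fry in limma 3.58.1. Fry's directional test asks whether a list moves on balance one way and its mixed test whether members change in either direction, and neither compares a list with other genes. The lists, the tests, the 73 alternatives and the rule for named genes were fixed before the data were examined. That rule took genes with an adjusted p under 0.05, at least 20 CPM in the higher group and no overlap between the groups' sets (in paired comparisons, the same sign in every set), and kept those with the largest log2 fold change per direction. It kept 12 for the reporter lines and the classes, 10 for each line against wild type and 5 for age, and up to 3 peptide, receptor or transmission genes per neuron type. Members of the fixed lists could be named as well, and single results of some of them are not reported here. A gene with 0 counts in a group is given by its bound against the floor, and a gene with 1 to 3 counts by the ratio of pooled rates with an exact 95% counting interval. The list medians of the reporter comparison did not move with genes at 0 set to their bound.

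Alternatives comprised DESeq2 1.42.0, its factors within edgeR, no composition factors, no filter or a filter of 20 CPM, limma on log2 of mean single-cell CPM plus 5, limma with types weighted equally, capture runs of at least 3 cells as units, age as a covariate, at least 20 cells per set, no replicate block, and leaving out each animal set. A further 8 were added after the results were seen: 5 with the share of cells with an Xist UMI as a covariate, 2 with limma and types weighted by their cells, and 1 with the 22-day wild-type sets summed. The tests across genes, and not the tests of type shares, were tested on simulated data. In these 100 genes changed 2-fold and 100 changed 4-fold, and for neuron types 22 and 24 list genes in an excitatory and 28 and 27 in an inhibitory type. EdgeR recovered 53% and 94% of them for the reporter lines (13.0% of calls false), 65% and 97% for the classes (7.43% false), 71% and 98% for the vGat line (6.63% false) and 48% and 94% for the vGlut2 line (8.39% false). For age it recovered 19% and 65% in inhibitory cells (9.68% false) and 20% and 81% in excitatory cells (0.98% false), and for the conflicting type 7% and 39% against excitatory cells (4.17% false) and 5% and 61% against inhibitory cells (2.94% false). The interaction terms recovered 16% and 70% for the class difference (8.51% false) and 5% and 31% for the age slope (5.26% false). For neuron types 36.4% and 100% were recovered in excitatory and 35.7% and 100% in inhibitory types. Further tools were the R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.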

Results

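Single-cell RNA sequencing was carried out on neurons of the mouse dorsal horn, the part of the spinal cord that receives pain, itch and touch fibres. The series holds 1545 cells, each with a molecule (UMI) count for 24378 genes. Of these, 637 came from C57bl6 wild-type mice, 537 from a vGat-Cre-tdTomato line, in which the vesicular GABA transporter gene drives the marking of inhibitory neurons, and 371 from a vGlut2-eGFP line, in which the vesicular glutamate transporter gene drives green fluorescence in excitatory neurons. The median cell held 8687 UMIs in wild type (range 3058 to 32886), 10413 in the vGat line (3707 to 22498) and 7030 in the vGlut2 line (3012 to 20050). The authors annotated 30 neuron types, 15 of them excitatory and 14 inhibitory, while 1 type carries labels of both kinds. The labels name no animals, so cells of the same line, sex label and age label were summed into 17 animal sets (10 wild type, 3 vGat, 4 vGlut2), which served as replicates. An animal set may hold several mice, the pair of 22-day wild-type sets may share mice, and p-values therefore measure the spread between animal sets. Levels are given in CPM, UMI counts scaled to each set's total, as mean ± SD over animal sets. Numbers of changed genes over all genes are mostly given as percentages of the genes tested in each comparison.

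Sex-linked transcripts did not follow the sex labels. Xist, the RNA that silences an X chromosome in cells with a pair of them, had a UMI in 871 of the 1490 cells labelled male (58.5%). A UMI of a Y-linked gene (Ddx3y, Eif2s3y, Kdm5d or Uty) was seen in 39.9% of these cells, both kinds in 26 and neither in 50. Among 43 capture runs labelled male with at least 10 cells, 31 had Xist in at least 90% of cells, and 12 had Xist in at most 10% with Y-linked genes in at least 75%. Of the 16 sets labelled male, 6 had Xist in at least 90% of cells, 6 in at most 10%, and 4 lay in between. In 5 of the 16, single runs of at least 3 cells lay on both sides of these bounds, so these sets held more than 1 mouse. All 55 cells of the set labelled female had an Xist UMI and none a Y-linked UMI (0). In the vGat line the 17-day set had Xist in 99.4% of cells, the 18-day set in 0% and the 24-day set in 0.662%, and in the vGlut2 line the 25-day and 26-day sets had 100% and 94.1% while the 23-day and 24-day sets had 0%. The sets are therefore called by their labels below, and the sex label is not used as a measured sex.

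**Figure D1:**
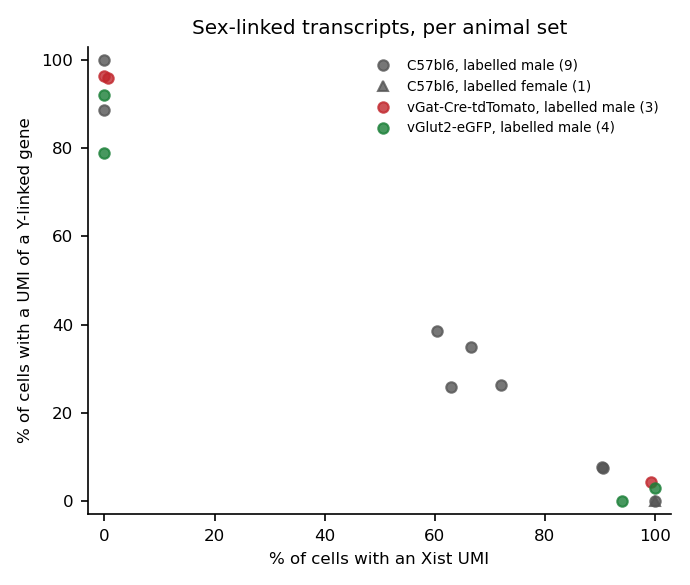
Percentage of cells with a UMI of a Y-linked gene (vertical axis) against the percentage with an Xist UMI (horizontal axis), with 1 point for each of 17 animal sets, coloured by line and shaped by sex label. Of the sets labelled male, 6 lie at 90% Xist or above, 6 at 10% or below and 4 between.

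The comparison of the reporter lines asks which genes separate inhibitory from excitatory dorsal horn neurons when cells are grouped by genotype. No capture run held cells of both lines, so line and capture run cannot be told apart in this comparison. Slc17a6, which encodes the glutamate transporter behind the vGlut2 reporter, stood at 0.628 ± 0.582 CPM in the vGat line (n = 3 sets) and 1152 ± 382.99 CPM in the vGlut2 line (n = 4), a log2 difference of -10.54 (SE 0.47, edgeR adjusted p = 2.91e-09). Gad1 encodes an enzyme that makes GABA and stood at 817 ± 60.6 CPM in the vGat line and 36.9 ± 71.8 CPM in the vGlut2 line (log2 difference 5.48, SE 0.91, adjusted p = 0.000741). Without the 26-day vGlut2 set, Gad1 had 3 counts in that line (0 to 2.17 CPM in the sets) and the fitted difference was 9.30, and with DESeq2 the call was lost (4.30, adjusted p = 0.168). Pax2, a transcription factor of inhibitory dorsal horn neurons, was higher in the vGat line by 6.08 (SE 0.38; 110 ± 7.14 against 1.95 ± 2.98 CPM). Sst, the precursor of somatostatin, was lower by -6.10 (SE 0.39; 114.6 ± 20.8 against 7753 ± 3436 CPM). Of 10598 genes tested, 4.32% (458) were higher and 4.53% (480) lower in the vGat line at an adjusted p under 0.05, and 3.13% and 3.45% were so by at least 2-fold.

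Among the other genes with the largest decreases in the vGat line were peptides and their receptors. Nmu, the precursor of neuromedin U, had 1 count in the vGat line and 1191 ± 680 CPM in the vGlut2 line, a ratio of pooled counts of 8781 (95% counting interval 1575 to 346900). Its receptor gene Nmur2 had 0 counts in the vGat line against 32.97 ± 21.0 CPM, at least 62.98-fold lower against a floor of 3 counts over the group. Adcyap1, the precursor of the peptide PACAP, had 3 counts against 156.5 ± 80.5 CPM (ratio 421.3, interval 143.45 to 2049). Nts, the neurotensin precursor, stood at 3.71 ± 1.23 against 369.35 ± 243.2 CPM (log2 difference -6.61, SE 0.52). Cacna2d1, which encodes the calcium channel subunit that binds gabapentin, had 3 counts against 405.65 ± 176.05 CPM (ratio 891, interval 304.2 to 4327). Nrn1, which encodes neuritin, was lower by -8.12 (SE 0.48; 0.894 ± 1.55 against 344.1 ± 97.5 CPM). Cbln1, a synapse organiser, was lower by -6.02 (SE 0.43). Mia was lower by -6.56 (SE 0.46). Angpt4 had 1 count (ratio 177.5, interval 30.99 to 7094) and Crhbp, which encodes a binding protein for corticotropin-releasing hormone, 2 counts (ratio 113.3, interval 30.6 to 948). Genes with the largest increases included further transcription factors. Sall3 was higher in the vGat line by 7.09 (SE 0.54; 233.7 ± 24.8 against 4.84 ± 9.35 CPM). Neurod1, at 28.8 ± 7.34 CPM, had 0 counts in the vGlut2 line and was at least 25.7-fold higher. Lhx1 and Lhx5, which act in the inhibitory lineage, had 2 counts each in the vGlut2 line, with ratios of 89.6 (interval 24.6 to 742) and 57.3 (interval 15.7 to 475.7). Nr2f2 had 1 count (ratio 188.45, interval 33.6 to 7462), Neurod2 and Neurod6 had 2 each (ratios 45.6 and 71.1, intervals 12.5 to 379.1 and 19.5 to 590). Krt17, a keratin that marks a dorsal horn population, and Nxph2 had 1 count each (ratios 171.15 and 56.1, intervals 30.5 to 6778 and 9.88 to 2235). Gm14204 was higher by 5.73 (SE 0.76). Without the 26-day vGlut2 set Gm14204, Lhx1, Neurod2 and Nr2f2 had 0 counts in the vGlut2 line, and Lhx5 a ratio of 107.8. Without the 25-day set Krt17, Neurod6 and Nxph2 had 0 and were at least 13.5-fold, 12.9-fold and 5.35-fold higher in the vGat line. In that setting the ratios of Lhx1, Lhx5, Neurod2 and Nr2f2 were 24.2, 30.96, 12.3 and 50.9, that of Adcyap1 237.4, and the bound of Neurod1 was 6.95-fold. Without the 18-day vGat set Nmu and Adcyap1 had 0 counts, at least 1239-fold and 162.7-fold lower, Nmur2 was at least 34.3-fold lower, and Angpt4 and Krt17 had ratios of 96.6 and 112.5. Angpt4 had 0 counts without the 17-day vGat set and was at least 34.9-fold lower, and Crhbp had a ratio of 172.8 without the 24-day one. DESeq2 did not call Gm14204, Lhx1 or Neurod2 (adjusted p = 0.500, 0.0822 and 0.243), and limma on single-cell means did not call Angpt4 or Neurod2 (0.0517 and 0.0854).

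**Figure D2:**
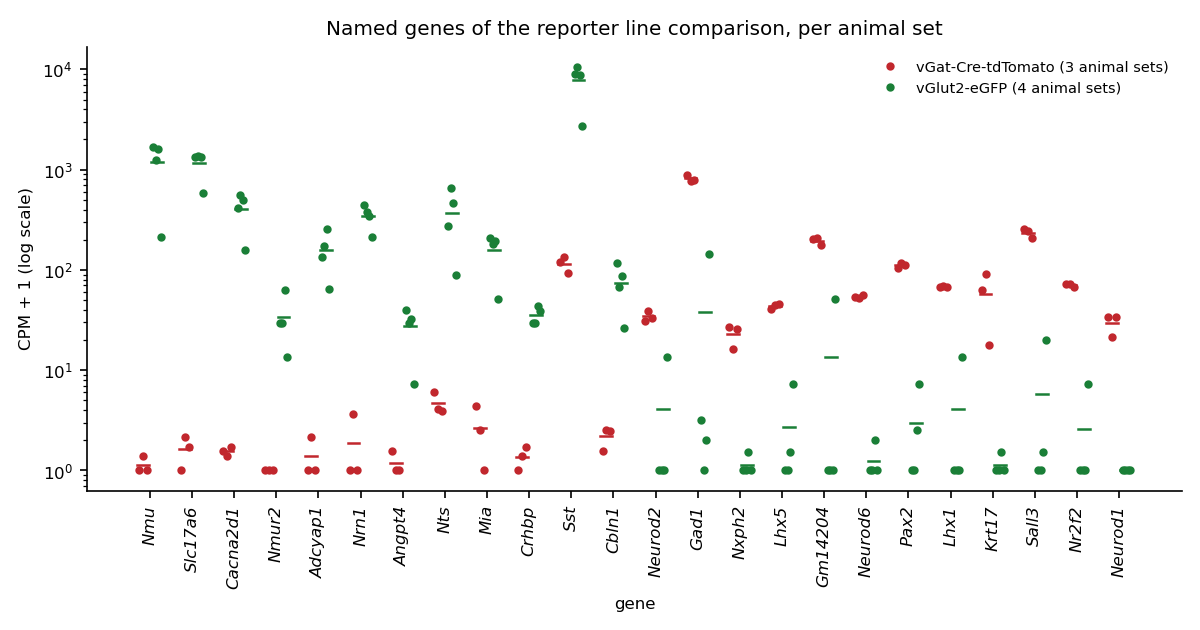
CPM plus 1, on a log axis, of the 24 named genes of the reporter line comparison, with 1 point per animal set (3 vGat sets in red, 4 vGlut2 sets in green) and a bar at the mean. The 26-day vGlut2 set lies apart from the other vGlut2 sets in several genes, for example Gad1 at 144.6 CPM and Slc17a6 at 578.3 CPM.

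The gene lists gave the following picture for the reporter lines. All 6 measured genes of GABA and glycine transmission rose in the vGat line (6 also when adjusted over the list alone), among them Gad2 (4.98), Slc32a1, the vesicular transporter behind the vGat reporter (4.71), and Slc6a5, the neuronal glycine transporter (3.28). The list passed the set test (camera adjusted p = 2.55e-09), but not with an estimated correlation (adjusted p = 0.0821 with an estimated correlation). All 7 measured inhibitory lineage transcription factors rose (7 adjusted over the list alone), including Rorb (4.16) and Pax8 (4.59), and this list held (adjusted p = 0.0310 with an estimated correlation). Of 8 excitatory lineage transcription factors 4 fell (5 adjusted over the list alone), with Pou4f1, at 2 counts in the vGat line, Prrxl1 (-3.80), Ebf2 (-3.41) and Tlx3, at 0 counts and at least 36.7-fold lower (adjusted p = 0.105 with an estimated correlation). Of 22 neuropeptide precursors 14 fell and 3 rose (14 and 5 adjusted over the list alone). Those that fell included Cck (-5.73), Grp, the gastrin-releasing peptide linked to itch (-5.86), Tac2 (-5.55) and Tac1, the substance P precursor (-1.58), and those that rose were Pdyn, the dynorphin precursor (4.36), Pnoc (4.24) and Gal, the galanin precursor (3.16). This list held as well (adjusted p = 0.00197 with an estimated correlation). Synaptic vesicle release genes rose in 7 of 21 cases and fell in 1 (11 and 2 adjusted over the list alone), with Cplx2 at 1.95 and Sv2b at -1.37 (adjusted p = 0.0412 with an estimated correlation). The glutamate transmission list, with 2 measured genes, passed through Slc17a6 (adjusted p = 0.0310 with an estimated correlation). Calls were lost for Gad2 (3.63), Slc32a1 (3.35), Pnoc (3.43), Gal (2.85) and Sv2b (-1.24) with DESeq2, and for Slc6a5, Pou4f1, Prrxl1, Tlx3, Pdyn, Gal and Sv2b with limma on single-cell means. With age as a covariate Pou4f1, Prrxl1, Gal and Sv2b lost theirs, and with the Xist share Sv2b. Sv2b was also not called without the 18-day vGat set (-1.16) or the 25-day vGlut2 set (-1.02). Without the 25-day set Pdyn stood at 2.85 and the ratio of Pou4f1 was 23.7, and without the 26-day set Gal stood at 5.11. Tlx3 was at least 18.5-fold lower without the 24-day vGlut2 set and 19.98-fold without the 18-day vGat set, where Pou4f1 had 0 counts and was at least 9.43-fold lower.

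Other lists moved in both directions between the reporter lines. Of 50 ion channel genes 10 rose and 6 fell (15 and 8 adjusted over the list alone), led by Cacna2d3 at 5.08 (SE 0.31). Of 21 glutamate receptor genes 8 rose and 4 fell (9 and 6 adjusted over the list alone), with Grik3 at 3.99, Gria1 at 1.52 and Grin3a at -2.09. Of 17 GABA and glycine receptor genes 1 rose and 4 fell (2 and 5 adjusted over the list alone), with Gabrg1 at 1.46 and Gabra5 at -1.24. Of 19 neuropeptide and opioid receptor genes 5 rose, among them the somatostatin receptor genes Sstr2 (3.04) and Sstr1 (2.59), and 5 fell, among them Grpr, the receptor for gastrin-releasing peptide, with 3 counts in the vGat line (ratio 34.9, interval 11.3 to 175.2; 6 and 7 adjusted over the list alone). Dorsal horn population markers rose in 9 of 20 cases and fell in 7 (9 and 9 adjusted over the list alone), with Ret at 4.33, Crabp1 at 4.08 and Calb1 at -4.13. For these 5 lists camera gave adjusted p values from 0.121 to 0.997, and fry's test of change in either direction gave 0.00203 to 0.00754. Immediate early genes fell in 6 of 20 cases, with Atf3 at -4.99, Npas4 at -2.23 and Arc at -1.94 (9 fell and 2 rose adjusted over the list alone). Ribosomal protein genes fell in 5 of 77 (0 adjusted over the list alone). Both lists lost their call (adjusted p = 0.761 with an estimated correlation for each). Heat shock genes fell in 4 of 15 cases (Hspb1 at -4.29), growing neuron genes rose in 2 of 19, and nuclear respiratory chain genes fell in 2 of 38 (4, 2 and 1 adjusted over the lists alone). Of 8 neurofilament and perineuronal net genes and of 33 mitochondrially encoded genes 0 changed (0 adjusted over the lists alone), and camera called none of these 5 lists. Without the 25-day vGlut2 set Gabrg1 stood at 2.31 and Gabra5 was not called (-1.20), and without the 17-day vGat set the ratio of Grpr was 72.6. Limma on single-cell means did not call Gabra5, Sstr2, Grpr, Atf3 or Npas4, and age as a covariate did not call Npas4.

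Markers of other cells were measured beside these lists. The 26-day vGlut2 set held 17 cells, 5 of them annotated to inhibitory types, and its cells carried 29657 CPM of oligodendrocyte list genes against 86.99, 63.2 and 1465 CPM in the 23-day, 24-day and 25-day vGlut2 sets. Its line label was not verified, since the reporter transgenes have no entry in the table, and vGlut2 values over 4 sets rest on that label. None of the 10 oligodendrocyte genes changed between the reporter lines (0 called; median log2 difference -1.94, with both set tests pointing up at adjusted p = 0.997 and 0.992), and the median was 1.08 with 4 genes higher without the 26-day vGlut2 set. Of 4 astrocyte genes 0 changed (2 higher and 1 lower adjusted over the list alone), of 2 oligodendrocyte precursor genes 0, and of 1 microglial gene 0, while the 1 measured endothelial gene, Itm2a, fell (-2.07). Pericyte and fibroblast, ependymal, ganglion sensory neuron and motor neuron lists had 0 genes above the count filter in this comparison. Median, mean and test also differed in sign for the receptor, astrocyte and respiratory chain lists, none of which was called. Without the 17-day vGat set 2.85% of genes were higher and 2.93% lower, without the 18-day vGat set 2.39% and 2.68%, without the 25-day vGlut2 set 1.88% and 1.99%, without the 26-day vGlut2 set 7.02% and 6.92%, and without the 23-day vGlut2 set 2.95% lower. With age as a covariate 1.755% were higher and 1.36% lower, and on simulated data of this design 13.0% of called genes were false, above the nominal 5%.

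**Figure D3:**
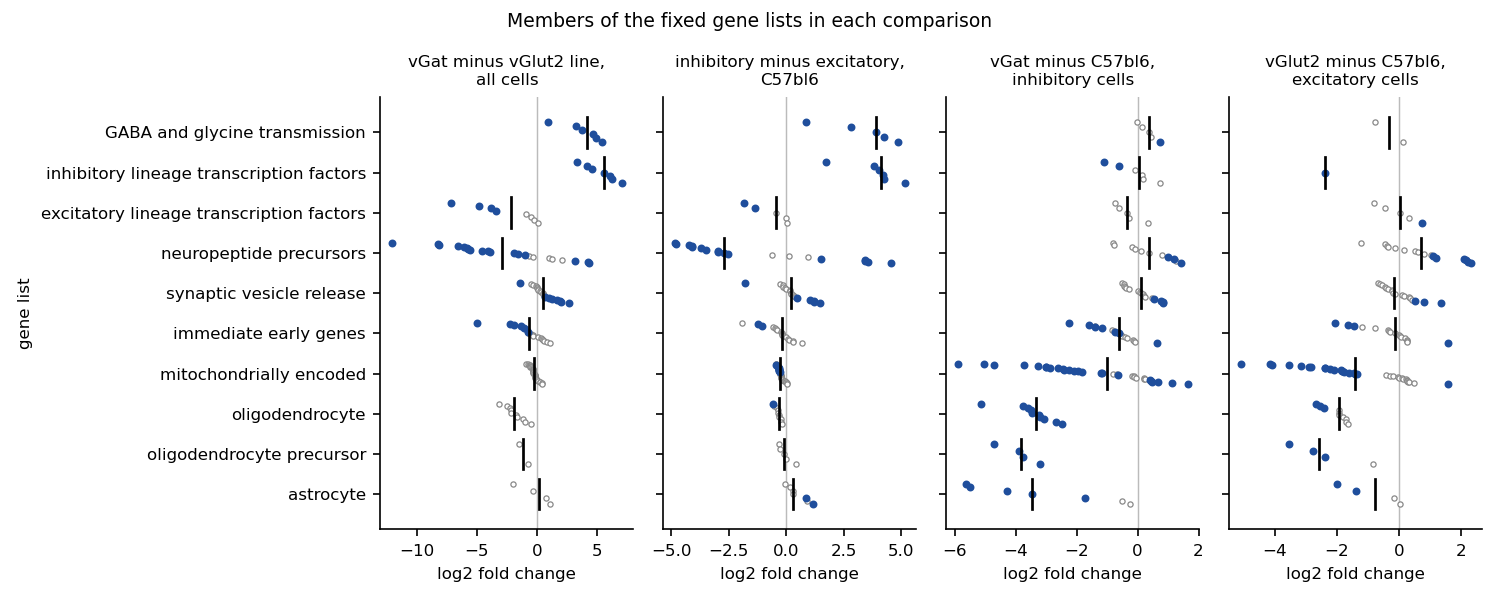
Log2 fold changes of the measured members of 10 gene lists in 4 comparisons (panels), with 1 point per gene, filled where the adjusted p was under 0.05 over all genes, and a bar at each list's median; each panel has its own axis range. In the reporter lines all 6 GABA and glycine transmission genes lie above 0, and in inhibitory cells of the vGat line against wild type all 10 oligodendrocyte genes lie below 0.

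Within wild type the annotated classes were compared in the 7 animal sets with at least 10 cells of each class, with the animal set as a block. The study assigned the classes from these cells, so genes that define a class are not independent evidence of its direction. Gad1 stood at 784 ± 154.3 CPM in inhibitory and 26.7 ± 27.3 CPM in excitatory cells (n = 7 pairs; log2 difference 4.87, SE 0.29, adjusted p = 2.23e-10). Slc17a6 stood at 27.3 ± 14.5 and 431.99 ± 70.8 CPM (-4.07, SE 0.20, adjusted p = 5.21e-11). Sst was lower in inhibitory cells by -4.23 (SE 0.24; 187.4 ± 130.8 against 3277 ± 701 CPM). Tac2 was lower by -4.85 (SE 0.36; 26.4 ± 47.7 against 604.9 ± 305.4 CPM). Pnoc, the precursor of the opioid-like peptide nociceptin, was higher by 4.56 (SE 0.29; 306.7 ± 76.8 against 10.5 ± 9.83 CPM). Of 8135 genes 3.17% were higher and 2.46% (200) lower in inhibitory cells, and 1.86% and 1.48% were so by at least 2-fold.

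The remaining genes with the largest increases in wild-type inhibitory cells were Pax2 (5.15), Lgals9, which encodes galectin-9 (4.58), Gad2 (4.26), Sall3 (4.23), Neurod2 (4.22), Pax8 (4.21), Lhx5 (4.02), 1500016L03Rik, Slc32a1 (3.91) and Gm5, with 3 counts in excitatory cells (ratio 40.4, interval 13.4 to 200). Those with the largest decreases were Cck (-4.78), Nrn1 (-4.74), Trh, the precursor of thyrotropin-releasing hormone (-4.09), Grpr (-4.00), the growth factor gene Bdnf (-3.97) and Nell1 (-3.93). Rprm and A730046J19Rik had 2 counts each in inhibitory cells and Nmur2 1 count, with ratios of 42.8 (interval 11.6 to 357.4), 25.0 (6.68 to 210) and 54.1 (9.43 to 2164). Each of these 24 genes differed in the same direction in 7 of 7 sets, which the rule for naming them required. The 5 measured GABA and glycine transmission genes all rose, as did all 6 inhibitory lineage factors (5 and 6 adjusted over the lists alone; adjusted p = 0.000505 with an estimated correlation for each). Of 19 neuropeptide precursors 11 fell and 5 rose (12 and 6 adjusted over the list alone; adjusted p = 0.0307 with an estimated correlation), with Npy at 3.54, Pdyn at 3.42 and Gal at 3.404 among those that rose. The glutamate transmission list passed through Slc17a6 among its 2 genes (adjusted p = 0.00206 with an estimated correlation). Pdyn lost its call without the 18-day (3.00) or the 19-day set (2.86), with DESeq2 and with at least 20 cells per set. The ratio of Gm5 was 23.5, 25.6 and 115.2 without the 19-day, 20-day and 26-day sets, and that of A730046J19Rik 46.1 and 48.2 without the 19-day and 21-day sets. Rprm had 0 counts in inhibitory cells without the 20-day set (at least 20.2-fold lower) and Nmur2 without the set labelled female (at least 12.8-fold lower).

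Of 18 synaptic vesicle release genes 5 rose, among them Cplx2 (1.47) and Syt1 (1.03), and Sv2b fell (-1.81; 7 and 2 adjusted over the list alone; adjusted p = 0.136 with an estimated correlation). Mitochondrially encoded genes fell in 9 of 34 cases, led by mt-Co1 at -0.45 (14 adjusted over the list alone), ribosomal protein genes in 1 of 75, and excitatory lineage factors in 2 of 5, Ebf2 (-1.86) and Maf (-1.35; 0 ribosomal and 3 lineage genes adjusted over the lists alone), and for each of these 3 lists adjusted p = 0.291 with an estimated correlation. Camera also called the immediate early, respiratory chain, astrocyte and oligodendrocyte lists, in which Nr4a1 (-1.06) and Npas4 (-1.23) fell, 0 of 38 genes changed, 2 astrocyte genes rose, among them Aldoc (0.87), and Mag (-0.57) fell (5 immediate early and 2 oligodendrocyte genes lower, 2 astrocyte genes higher adjusted over the lists alone), and these calls were lost (adjusted p from 0.493 to 0.524 with an estimated correlation). In both directions, ion channel genes rose in 7 and fell in 4 of 42 cases (Cacna2d3 at 2.63, Cacna2d1 at -3.12), glutamate receptor genes in 4 and 3 of 15 (Grik3 at 2.84, Grin3a at -1.91), population markers in 6 and 7 of 17 (Crabp1 at 3.75, Calb1 at -2.85), peptide receptors in 3 and 2 of 13 (Sstr2 at 3.397), and growing neuron genes in 3 and 1 of 19. The counts adjusted over the list alone were 7 and 6, 5 and 3, 9 and 8, 3 and 2, and 6 and 2. Of 15 GABA and glycine receptor genes, 15 heat shock genes, 7 neurofilament genes and 5 oligodendrocyte precursor genes 0 changed. Median, mean and test differed in sign for the peptide receptor and population marker lists. Without the animal set as a replicate block 1.66% of genes were higher and 1.303% lower (2.19% and 1.72% of the 6170 tested there), and Maf, Aldoc and mt-Co1 were not called. Calls were lost for Sv2b (-1.48) and Aldoc (0.72) without the 20-day set, for Aldoc (0.75) without the set labelled female and for Maf (-1.16) without the 26-day set. They were also lost for Aldoc and Npas4 with DESeq2, for Maf and Sv2b with limma on single-cell means, for Aldoc, Mag and Nr4a1 with at least 20 cells per set, and for Mag with the conflicting type counted as inhibitory.

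Transcripts of the other class were seen in single cells. With every cell thinned to 3000 UMIs, which left out 0 cells, Slc17a6 had a UMI in 5.02% of wild-type inhibitory cells (11 cells, exact 95% interval 2.53 to 8.81%; 13.7% unthinned; median depth 10614 UMIs) and 0.373% of inhibitory cells of the vGat line (2 cells, interval 0.0452 to 1.34%; 0.373% unthinned; 10416 UMIs). The share was 67.8% in wild-type excitatory cells (90.5% unthinned; 8014 UMIs) and 94.5% in those of the vGlut2 line (98.4% unthinned; 7021 UMIs). Gad1 had a UMI in 3.99% of wild-type excitatory cells and 0.548% of excitatory cells of the vGlut2 line.

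The class difference between the reporter lines was set against that within wild type by an interaction term. This term used inhibitory cells of the vGat line and excitatory cells of the vGlut2 line, where the reporter line comparison used all cells. Its values are therefore not the differences of the log2 values given above. Of 9102 genes, 7 had a larger and 15 a smaller (more negative) inhibitory-minus-excitatory difference in the reporter lines, and 5.97% had an unadjusted p under 0.05. The largest shifts were in Nmu (-8.47, SE 1.72), Gm14204 (6.69, SE 1.25), Slc17a6 (-6.44, SE 0.51), Nr2f2 (6.21, SE 1.34) and Cacna2d1 (-6.13, SE 0.59), and the others included Adcyap1 (-5.17), Mia (-4.88), the astrocyte gene Gja1 (-4.84), Sall3 (3.64), Grp (-3.23), Gad2 (3.16), Cacna2d3 (2.52) and Rorb (2.38). Line and capture run differ together between the reporter cells and wild type, and age was not adjusted for in this term. The animal set was not a block in it, so inhibitory and excitatory sums of the same wild-type sets were treated as independent.

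Inhibitory cells of the vGat line (3 sets) were then compared with wild-type inhibitory cells (7 sets). Markers of myelin-forming oligodendrocytes were lower in the vGat line throughout: Mbp, which encodes myelin basic protein, by -2.47 (SE 0.33, adjusted p = 4.88e-06), Mog by -3.24 and Apod by -5.14. All 10 oligodendrocyte genes fell (10 adjusted over the list alone; median -3.35; adjusted p = 0.0162 with an estimated correlation), as did all 4 oligodendrocyte precursor genes, with Olig1 at -3.90, Sox10 at -3.76 and Olig2 at -4.71 (4 adjusted over the list alone; median -3.83; adjusted p = 0.0134 with an estimated correlation). Of 7 astrocyte genes 5 fell (6 adjusted over the list alone; adjusted p = 0.293 with an estimated correlation), among them Aqp4 at -4.28, Apoe at -3.47, Gja1 with 2 counts in the vGat line (ratio 69.3, interval 18.3 to 586.3) and Slc1a3 with 2 counts (ratio 57.2, interval 14.97 to 485.9). Aqp4 was not called by limma with single-cell means or with types weighted in either way, nor Slc1a3 with single-cell means. Slc1a3 had 0 counts without the 17-day vGat set and a ratio of 31.1 without the 18-day one, and Gja1 a ratio of 105.7 without the 24-day one. Of 7687 genes 8.34% (641) were higher and 12.9% (989) lower in the vGat line, and 1.38% and 8.59% were so by at least 2-fold. Without composition factors 11.3% (869) were higher and 11.6% (889) lower, so that 49.4% of the changed genes were higher in place of 39.3%.

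The genes with the largest decreases in the vGat line included transcripts of red blood cells and myelin. Hbb-bs, a beta-globin gene, had 0 counts against 105.3 ± 161.5 CPM in wild type, at least 200.9-fold lower. The alpha-globin copies Hba-a2_loc2, with 0 counts and at least 148.6-fold lower, and Hba-a2_loc1, with 1 count (ratio 389.2, interval 68.9 to 15469), share near-identical sequence, so their separate counts are uncertain. Hapln2, a link protein at the nodes of myelinated axons, had 0 counts against 85.8 ± 74.8 CPM (at least 163.8-fold lower), and Klk6, a protease of oligodendrocytes, had 3 (ratio 180.8, interval 61.1 to 884). Ptgds, the prostaglandin D synthase gene, stood at 9.68 ± 6.12 against 1183 ± 1423 CPM (-6.99, SE 0.95). Anln at -5.87 (SE 0.64) and E330020D12Rik with 2 counts (ratio 77.8, interval 20.7 to 657) followed. Cacna2d1 had 3 counts (ratio 62.4, interval 20.6 to 309.4) and the mitochondrial transfer RNA gene mt-Ty was lower by -5.90 (SE 0.59). Those with the largest increases were Zfp932 (2.15), Cdr1 (2.10; 118.8 ± 89.1 against 22.9 ± 17.6 CPM), Gm14204 (1.91), Mir124a-2 (1.82), Akap5 (1.77), Lix1 (1.76), Mir1906-2_loc2 (1.74), Gm12191 (1.71), mt-Nd3, a subunit of respiratory complex I (1.64; 1415 ± 60.4 against 433.5 ± 53.4 CPM), and March1 (1.55). Without the wild-type set labelled female the bounds were 93.7-fold for Hbb-bs and 95.8-fold for Hba-a2_loc2, and the ratio of Hba-a2_loc1 was 246.1. Without the 18-day vGat set they were 109.3-fold and 80.8-fold, Hapln2 at least 89.1-fold lower, Hba-a2_loc1 at 211.7, and Klk6 had 0 counts, as Hba-a2_loc1 had without the 24-day set. Without the 24-day vGat set Cdr1 stood at 1.3005. Limma did not call Mir124a-2 with single-cell means or with types weighted in either way, nor Lix1 with types weighted equally.

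Among neuronal lists, Slc17a6 fell in the vGat line (-5.06, SE 0.66), and 1 of 5 GABA and glycine transmission genes rose (3 adjusted over the list alone). Neuropeptide genes rose in 3 of 11 cases (3 adjusted over the list alone), Npy (1.43), Calca, the precursor of the peptide CGRP (1.19), and Tac1 (0.98; camera adjusted p = 0.0945). Pax2 (-1.09) and Lhx5 (-0.61) fell among 6 inhibitory lineage factors (2 adjusted over the list alone) and 0 of 5 excitatory lineage factors changed. Immediate early genes fell in 6 of 17 cases, with Jund at -2.27, Arc at -1.59 and Junb at -1.40, while Homer1 rose (0.64; 8 fell and 1 rose adjusted over the list alone; adjusted p = 0.338 with an estimated correlation). Mitochondrially encoded genes fell in 18 of 34 cases, 17 of them transfer RNA genes such as mt-Tm (-5.04), and 6 protein-coding members such as mt-Nd4l (1.13) rose (20 and 7 adjusted over the list alone; adjusted p = 0.293 with an estimated correlation). Ribosomal protein genes moved both ways (15 of 76 higher, with Rpl23a at 1.26, and 11 lower, with Rpl13 at -1.52; 16 and 14 adjusted over the list alone). So did ion channels (4 of 43 higher, 9 lower, with Hcn2 at -3.02 and Kcna1 at -1.29; 4 and 10 adjusted over the list alone). Synaptic vesicle genes rose in 4 of 17 cases (Syp at 0.85), respiratory chain genes fell in 8 of 38, glutamate receptor genes rose in 4 and fell in 2 of 15, heat shock genes in 3 and 1 of 14, growing neuron genes in 2 and 3 of 19, GABA and glycine receptor genes in 2 and 1 of 14, peptide receptors rose in 2 of 10 and population markers in 1 of 13, with none of these 8 lists called by camera. Adjusted over the list alone, respiratory chain genes fell in 10 cases and glutamate receptor genes rose in 5, and the other 6 lists gave the counts above. Median and mean differed in sign for the inhibitory lineage, population marker, ion channel and neurofilament lists. Leaving out the 17-day, 18-day or 24-day vGat set left 3.49%, 4.15% or 3.27% of genes higher, and leaving out the 20-day wild-type set 5.52%. Limma fits gave 3.63% higher and 6.53% lower with types weighted by their cells, and 1.57% and 4.45% with types weighted equally. Homer1 lost its call when any of 8 of the 10 sets was left out (0.55 to 0.66), Lhx5 without the 27-day wild-type set or any vGat set (-0.57 to -0.66), and Calca without the 18-day vGat set (1.04). With types weighted equally Calca, Npy, Tac1, Arc, Homer1 and Lhx5 were not called, and with capture runs as units Npy and Tac1. With age as a covariate 7.36% of genes were higher and 12.5% lower, Homer1 and Lhx5 not among those called. Line and capture run cannot be told apart here.

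**Figure D4:**
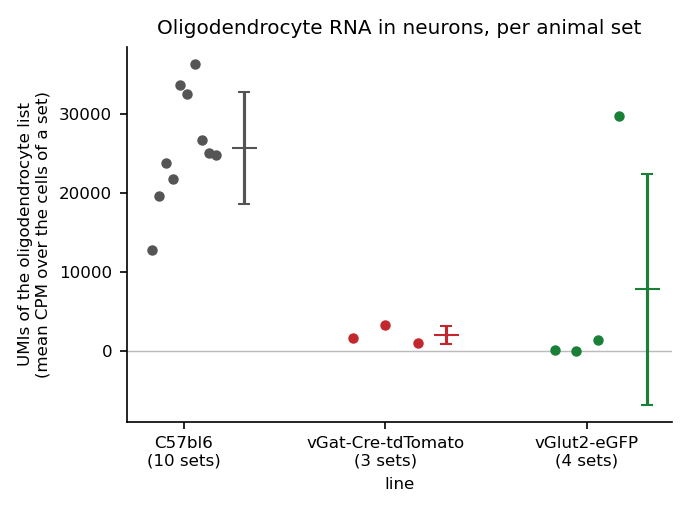
Mean CPM of the 10 oligodendrocyte list genes over the neurons of each animal set, with 1 point per set and the mean ± SD of each line beside it. Wild type lies at 25648 ± 7051 CPM (10 sets), the vGat line at 2012 ± 1120 CPM (3 sets) and the vGlut2 line at 7818 ± 14574 CPM (4 sets), where the 26-day set reaches 29657 CPM.

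Excitatory cells of the vGlut2 line (4 sets) were compared with wild-type excitatory cells (9 sets). Neuropeptide genes rose in 6 of 16 cases (7 higher and 1 lower adjusted over the list alone; median 0.71; adjusted p = 0.00412 with an estimated correlation). Grp was higher by 2.10 (SE 0.17; 335.7 ± 80.96 against 76.6 ± 14.003 CPM; adjusted p = 1.35e-07), Calca by 2.30 (SE 0.30; 245.3 ± 92.2 against 40.6 ± 22.3 CPM), Tac2 by 2.16 (SE 0.39; 3366 ± 1592 against 722 ± 477.2 CPM) and Nmu by 2.23 (SE 0.50), with Sst (1.198) and Adcyap1 (1.09) also higher. In limma fits the median of the 6 genes was 2.03 with types weighted by their cells and 1.12 with types weighted equally, with 6 and 3 of them called, and Tac2 (0.99), Nmu (1.26) and Sst (0.76) were not called with types weighted equally. Nmu was not called by limma on single-cell means (2.17), nor Adcyap1 without the 25-day vGlut2 set (0.73). Slc17a6 was higher by 1.42 (SE 0.16, adjusted p = 5.27e-06). Of 7163 genes 4.41% were higher and 10.7% (765) lower in the vGlut2 line, and 1.56% and 8.33% were so by at least 2-fold. Without composition factors 6.69% were higher and 9.31% (667) lower, so that 41.8% of the changed genes were higher in place of 29.2%.

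The genes with the largest decreases in the vGlut2 line were Fa2h, an enzyme of myelin lipid synthesis (-5.49, SE 0.51; 14.96 ± 26.9 against 274.3 ± 47.5 CPM), Myrf, a regulator of myelin genes (-4.18, SE 0.55), Elovl7 (-4.18), Tmem88b (-4.37), Anln (-5.26), Prr5l (-5.31), Pon2 (-4.44) and Gab1 (-4.19), with Nde1 at 3 counts (ratio 20.3, interval 6.72 to 100) and the transfer RNA gene mt-Tm at -5.09. The largest increases, besides Grp, Calca and Tac2, were in Mir7b (2.41), Mir124a-2 (1.90), Gm5424 (1.72), Rasl11a (1.71), Gm12191 (1.64), Entpd3 (1.63) and Gas5 (1.63). Oligodendrocyte genes fell in 3 of 10 cases, Mobp (-2.67), Mag (-2.55) and Ermn (-2.41; 5 adjusted over the list alone; median -1.92; adjusted p = 0.396 with an estimated correlation). Without the 26-day vGlut2 set all 10 were lower, with a median of -5.07. Mobp, Mag and Ermn were not called with DESeq2 or without the 25-day set (-2.24, -2.06 and -1.81), Mag and Ermn not without the 23-day (-1.99 and -1.79) or the 24-day set (-2.15 and -2.01), and Ermn not without the 19-day, 20-day or 27-day wild-type set (-2.31 to -2.38). Oligodendrocyte precursor genes fell in 3 of 4 cases (3 adjusted over the list alone; Sox10 at -3.53; adjusted p = 0.413 with an estimated correlation), and astrocyte genes in 2 of 4, among them Apoe (-1.40; 2 adjusted over the list alone), which lost its call in 10 of the 13 fits without a set (-0.89 to -2.06), without composition factors and with age or the Xist share as a covariate. With types weighted equally Tac2, Gm5424 (0.80), Rasl11a (1.16) and Entpd3 (1.29) were not called. Of the 20 genes picked by the naming rule, 1 lost its call with limma on single-cell means and 1 with types weighted by their cells.

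Mitochondrially encoded genes fell in 19 of 34 cases, each a transfer RNA gene, and mt-Nd3 rose (1.59; 20 and 1 adjusted over the list alone; adjusted p = 0.168 with an estimated correlation). Ribosomal protein genes rose in 15 of 75 cases, with Rps10 at 1.54, and fell in 5, with Rps26 at -1.26 (18 and 5 adjusted over the list alone; adjusted p = 0.599 with an estimated correlation). Heat shock genes rose in 4 of 15 cases, with Hspb1 at 1.71 and Dnajb1 at 1.39 (4 adjusted over the list alone; adjusted p = 0.296 with an estimated correlation). The glutamate transmission list, called by camera through Slc17a6, gave adjusted p = 0.168 with an estimated correlation. Ion channel genes fell in 6 of 38 cases, with Hcn2 at -2.92 and Kcna1 at -2.28, and rose in 2. Immediate early genes fell in 3 of 17, with Jund at -1.64, and rose in 1, Atf3 at 1.58, and population markers rose in 3 of 11, with Car12 at 1.61 (7 channels lower and 3 higher, 5 immediate early genes lower and 1 higher, and 4 markers higher adjusted over the lists alone). Synaptic vesicle genes rose in 3 of 18 cases, peptide receptors in 2 of 9, GABA and glycine receptors in 2 of 14, and growing neuron genes in 2 of 18 with 2 lower. Glutamate receptors rose in 1 of 15 with 1 lower, excitatory lineage factors in 1 of 5, Ebf2 (0.73), and Rorb, the 1 measured inhibitory lineage factor, fell (-2.37). Adjusted over the list alone, 1 synaptic vesicle gene was lower as well and 3 growing neuron genes were higher and 3 lower. Median and mean differed in sign for the synaptic vesicle, excitatory lineage and respiratory chain lists, and the pair of set tests for the glutamate receptors. Without the 23-day vGlut2 set 2.12% of genes were higher and 5.56% lower, and without the 25-day set 1.68% and 4.05%. In that fit Hspb1 (1.11), Dnajb1 (0.79), Atf3 (0.97), Ebf2 (0.56) and Rps26 (-1.27) were not called. Ebf2 was not called either without the 23-day vGlut2 set or the 18-day or 20-day wild-type set (0.66 to 0.71). DESeq2 did not call Dnajb1 or Atf3, and limma on single-cell means Hspb1, Dnajb1, Atf3, Ebf2 or Rorb. With types weighted equally Hspb1, Dnajb1, Atf3, Ebf2, Car12 and Rps26 were not called. Limma fits gave 3.895% higher and 8.39% lower with types weighted by their cells, and 1.59% and 5.85% with types weighted equally. With the 22-day wild-type sets summed, numbers equal to 5.99% and 11.8% of the genes above were higher and lower by edgeR. Both comparisons against wild type use the same wild-type mice, through different cells, so their shared genes are not counted here.

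Neuron types were compared with the other types of their class for the genes of the fixed lists only, leaving out the genes in each type's own name, since the study defined the types on these cells. Over 15 excitatory types 9.46% of 2940 gene and type pairs were higher and 3.47% lower, and over 14 inhibitory types 12.1% of 3276 pairs were higher and 4.76% lower. Nmu was higher in 2 excitatory types named for Tac2, Glut6 (log2 difference 5.81, SE 0.25; 3315 ± 1287 CPM against 386.1; 10 sets, 74 cells) and Glut7 (5.70, SE 0.26; 3279 ± 2277 against 390 CPM). Pthlh, which encodes a parathyroid hormone-like peptide, was higher in Glut5 (4.63, SE 0.51) and Glut6 (3.99, SE 0.36), and the stress peptide gene Ucn3 in Glut3 (4.85, SE 0.49). Gal was higher in Glut3 (5.21, SE 0.48; 583.5 ± 749 against 51.8 CPM), a type named for Cck and Trh, and in Glut14 (4.58, SE 0.46), where Cartpt (4.68, SE 0.47; 280 ± 280 against 17.5 CPM) and Tac1 (3.15, SE 0.36) were higher as well. Penk, the enkephalin precursor, was higher in Glut10 (2.08, SE 0.28; 917 ± 503.4 against 298.15 CPM), Grp in Glut8 (2.06, SE 0.32), Adcyap1 in Glut9 (1.98, SE 0.44), and Nppc in Glut2 (3.19, SE 0.42; 244.15 ± 95.5 against 34.9 CPM).

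Among inhibitory types, Gad1 was higher in Gaba14, a type named for Crabp1 (2.41, SE 0.15; 3174 ± 646 against 653 CPM; 7 sets, 40 cells), with the cholecystokinin receptor gene Cckbr (3.10, SE 0.45). Trhr, the receptor for thyrotropin-releasing hormone, was higher in Gaba6 (4.31, SE 0.32; 242.05 ± 120 against 20.2 CPM), as were Trh itself (4.57, SE 0.61; 72.4 ± 87.4 against 0.509 CPM) and Penk (2.36, SE 0.30). Pdyn was higher in Gaba3 (3.53, SE 0.35; 129.03 ± 97.7 against 13.8 CPM), Sstr1 in Gaba2 (3.20, SE 0.30) and Gaba3 (2.96, SE 0.31), and Tacr3, the neurokinin B receptor gene, in Gaba2 (3.23, SE 0.35). Nts was higher in Gaba5 (5.01, SE 0.72), Calca in Gaba8 (2.61, SE 0.28) and Npy2r in Gaba10 (2.27, SE 0.57). These values rest on the authors' clusters.

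Shares of the annotated types were compared between each reporter line and wild type with exact two-sided permutation tests over animal sets. Glut6 made up 16.4% ± 5.93 of excitatory cells in the vGlut2 line (n = 4 sets) and 5.16% ± 3.37 in wild type (n = 9; exact permutation p = 0.0014, the smallest possible over 715 splits; adjusted p = 0.0210). Glut7 made up 15.5% ± 7.59 against 5.004% ± 3.22 (exact permutation p = 0.0042; adjusted p = 0.0315). Both types are named for Tac2 and carry high Nmu. Glut10, named for Tac1, stood at 11.1% ± 3.60 against 21.0% ± 5.43, and Glut12 at 1.11% ± 1.99 against 8.88% ± 5.06, and neither passed (adjusted exact permutation p = 0.0559 and 0.0629). Of 14 inhibitory types 0 passed; the nearest was Gaba9 at 12.7% ± 1.37 in the vGat line against 7.29% ± 3.02 (exact permutation p = 0.025, adjusted p = 0.35), where the smallest possible p was 0.0083. Without the 23-day or the 25-day vGlut2 set 0 excitatory types were called, where the smallest possible p was 0.00455 over 15 types; Glut6 then differed by 8.58 and 12.07 percentage points and Glut7 by 9.59 and 7.41, against 11.3 and 10.5 with all sets. Glut7 also lost its call without the 24-day set (12.2 points). Among sets with at least 20 cells, 2 vGlut2 sets allowed no p under 0.0222, and the differences were 14.5 and 16.01 points. The reporter, the choice of cells and the capture run can each set these shares.

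**Figure D5:**
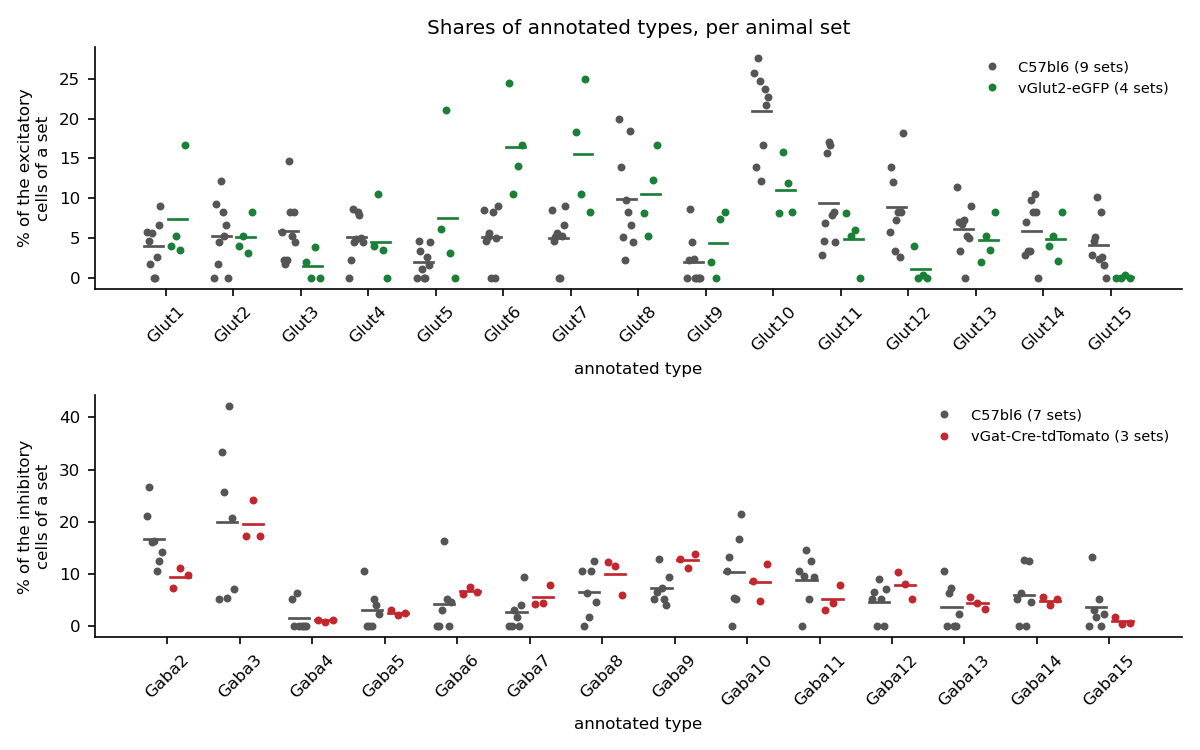
Percentage of the cells of a class that belong to each annotated type, with 1 point per animal set and a bar at the mean, for excitatory types (top; 9 wild-type and 4 vGlut2 sets) and inhibitory types (bottom; 7 wild-type and 3 vGat sets). Glut6 and Glut7 averaged 16.4% and 15.5% in the vGlut2 line against 5.16% and 5.004% in wild type.

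Age trends were fitted within wild-type sets labelled male, over 6 sets for inhibitory and 8 for excitatory cells. With ages reassigned among the sets, 11 of 100 splits in inhibitory and 24 of 100 in excitatory cells gave as many genes, so chance cannot be excluded. The classes share sets, so slopes of a gene in both are not independent. Ptgds was also among the genes with the largest decreases in the vGat line against wild type. In inhibitory cells Cartpt, the precursor of the CART peptide, rose by 0.45 per day on the log2 scale (SE 0.049, adjusted p = 7.02e-07) and Ptgds by 0.42 (SE 0.041, adjusted p = 2.02e-07), while Gm9846 fell (-0.21 per day, SE 0.040, adjusted p = 0.0328). In excitatory cells Ptgds rose by 0.40 (SE 0.048, adjusted p = 7.55e-05) and Gm9846 fell (-0.20, SE 0.036, adjusted p = 0.0335). No other gene passed among 6352 and 7424 tested, where 2.55% were higher and 4.12% lower, and 3.42% higher and 4.86% lower, at an unadjusted p under 0.05. In inhibitory cells camera called 5 lists, all with negative median slopes except the oligodendrocyte list (0.029): respiratory chain (-0.062), astrocyte (-0.13), ribosomal (-0.032) and mitochondrially encoded (-0.028). In excitatory cells it called 4, the respiratory chain (-0.051), ribosomal (-0.033), oligodendrocyte (-0.033) and excitatory lineage lists (0.058). Of these 9 calls 0 held, with adjusted p from 0.662 to 0.756 with an estimated correlation in inhibitory cells and from 0.402 to 0.672 in excitatory cells. With DESeq2 Cartpt had no adjusted p (slope 0.47), and without the 27-day set it was not tested. The Gm9846 call was lost in both classes without the 19-day, the 26-day or the 27-day set, with limma on single-cell means and with the set labelled female included. It was also lost in inhibitory cells with a filter of 20 CPM, and in excitatory cells without the 28-day set and with the Xist share as a covariate. In inhibitory cells 4 genes rose without the 19-day or the 20-day set, 1 rose without the 27-day set and 2 fell without the 18-day set. In excitatory cells 3 rose without the 21-day set, 2 without the 28-day set, and 4 fell without the 18-day set. The slopes of the classes were not shown to differ (edgeR interaction, 0 of 8499 genes, 3.47% at an unadjusted p under 0.05).

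Cells of 1 type carry labels that disagree, a GABA cell type name with a cluster name for glutamate and galanin. In 5 wild-type sets 14 such cells were compared with the other cells of the same sets. Against excitatory cells Gad2 was higher by 3.26 (SE 0.73; 146.3 ± 99.4 against 12.5 CPM; higher in 5 of 5 sets), Slc32a1 by 2.75 (SE 0.84) and Gad1 by 2.28 (SE 0.66), while Slc17a6 was lower by -2.58 (SE 0.52; 95.5 ± 153.6 against 418.5 ± 68.6 CPM; lower in 4 of 5 sets). The Gad1 call was lost without the 18-day set (1.72). Of 12 transmission and lineage genes 3 were higher and 4 lower adjusted over the list alone, the latter with Ebf1 (-1.68) and Ebf2, which had 1 count. Ebf1 was not called with DESeq2 or without the 18-day (-1.19) or the 21-day set (-1.28), and stood at -3.02 without the 19-day set. Against inhibitory cells Gad1 was lower by -2.50 (SE 0.44; 141.7 ± 88.9 against 776 ± 133.05 CPM) and Rorb by -2.38 (SE 0.65; -3.66 without the 27-day set). Pax2 had 2 counts and Sall3 0 against 195.95 ± 38.1 CPM (at least 8.11-fold lower), and of 12 such genes 0 were higher and 5 lower. Over all genes 7 were higher and 61 lower than in excitatory cells, of 5736 tested, and 52 higher and 72 lower than in inhibitory cells, of 2882. In these cells the oligodendrocyte gene Mbp stood at 3905 ± 1725 CPM, against 1896 ± 504.9 in excitatory (log2 difference 0.61, SE 0.35, not past the threshold) and 1532 ± 166.9 in inhibitory cells (1.22, SE 0.37, adjusted p = 0.0262 by edgeR). Against excitatory cells, 1.06% of genes were lower, and without the 19-day, 20-day, 21-day or 27-day set 0.523%, 1.90%, 0.471% or 0.401%, while 0.122% were higher, and 0.0697% without the 20-day and 0.0523% without the 27-day set. Against inhibitory cells, 1.80% were higher and 2.498% lower, and without the 18-day, 19-day, 20-day or 21-day set 0.278%, 0.798%, 3.33% or 0.416% were higher and 1.145%, 1.49%, 4.58% or 1.21% lower, with 1.11% lower without the 27-day set.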

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

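Of the tests in this part, those of depth, of free RNA, of the mix of types, of dilution and of annotation errors with all UMIs were chosen only after the result was seen, and the spread that the tests of mixing and of thinned annotation errors had to exceed was set after their values were seen. The bound for free RNA was moved from 0.5 to 0.8 of the mean after its values were seen. The move changes the reading for capture runs, so no conclusion is drawn for them.

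All 10 oligodendrocyte genes were lower in the vGat line than in wild type. In the vGlut2 line 3 of 10 were called lower, the list gave adjusted p = 0.396 with an estimated correlation, and the 26-day set (29657 CPM) stood above the wild-type mean (25648 CPM) while the other 3 sets held 63.2 to 1465 CPM. A difference in depth is argued against as the whole cause in the vGat line and in the 23-day to 25-day vGlut2 sets. Against wild-type cells of the same depth, in 4 bins of total UMIs, the log2 ratio of the oligodendrocyte share was -3.83 in the vGat line (interval over resampled sets -4.44 to -3.31) and -4.87 in these vGlut2 sets (interval -8.18 to -3.26; -7.82 without the 25-day set). With the 26-day set the ratio was -1.16 (interval -7.82 to 0.12; -0.52 without the 23-day set). In wild type the share rose from 5551 CPM in the bin of cells with the fewest UMIs to 43839 CPM in that with the most. Free RNA at 1 level in all wild-type cells is argued against, since the median cell of a set held 0.189 of the set's mean share (interval 0.0949 to 0.290), where equal levels need a median near the mean. The tenth of cells with the most held 3.08 times its Poisson share (interval 2.87 to 3.32). On free RNA at 1 level within each run no conclusion is drawn. The median cell of a run held 0.194 of the run's mean (interval 0.130 to 0.603; under 0.5 in 33 of 52 runs), where counting noise at equal levels gives 0.996, and the tenth of cells with the most held 1.66 times its Poisson share (interval 1.58 to 1.77). RNA of oligodendrocytes that reached wild-type cells unevenly stays open. A test fixed before the data were examined asked whether neuron types held a higher mean oligodendrocyte share in wild type. Each type with at least 5 cells in wild type and in the reporter lines did. A difference between lines would give the same outcome, so this test cannot decide. Line, capture run and cell selection are confounded, and a biological difference between lines stays open as untested.

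Excitatory genes were seen in wild-type inhibitory cells. Annotation errors stay open. Of 30 inhibitory cells with a Slc17a6 UMI 0% (upper limit 11.6%) lacked a UMI of Gad1, Gad2 and Slc32a1, but so did 0% of the other inhibitory cells, which were annotated from such genes, so the measure could not differ. After thinning 2 cells with at least 2 UMIs (0% without) were too few. RNA of excitatory neurons mixed into these captures may be the source, and stays open. Of the 12 named genes lower in the vGat line 4 (3 to 5 leaving out a set) had intervals that left out the median ratio of 10.3% between inhibitory and excitatory cells, where a single source would keep the ratio alike. No biological explanation was tested.

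Neuropeptide genes were higher in the vGlut2 line than in wild type. Dilution of neuronal RNA in wild type would raise neuronal genes alike, and stays open. The median of the peptide list (0.71) lay 0.85 above that of the ion channel list (interval over resampled genes -0.03 to 1.60) and 0.87 above that of the synaptic vesicle list (-0.13 to 1.52), and both intervals reach 0. Another mix of neuron types may account for part, and stays open. In limma fits the median of the 6 called genes was 2.03 with types weighted by their cells. It was 1.12 (0.553 of it) with equal weights, between the bounds set for either reading. Line and capture run are confounded, and a biological difference between lines stays open as untested.

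Of the groups of 4 to 10 sets examined, 35 (24.8%) held a set far from the others. Chance alone gives about 1 in 20 by the test's nominal rate, which need not hold for the 9 of them with counts in that set alone. The 26-day vGlut2 set was highest of its line in Lhx1 and Neurod2 (12.6 CPM each), Sall3 (18.9 CPM), Gad1 (144.6 CPM), Gm14204 (50.3 CPM), Lhx5 and Nr2f2 (6.29 CPM each), and lowest in Mia (50.3 CPM) and Slc17a6 (578.3 CPM). Among its excitatory cells it was highest in Elovl7 (73.7 CPM), Myrf (36.8 CPM), Prr5l and Anln (27.6 CPM each), Tmem88b (147.3 CPM), Pon2 (18.4 CPM) and Fa2h (55.2 CPM). The 25-day vGlut2 set was highest in Krt17 and Nxph2 (0.511 CPM each) and Neurod6 (1.02 CPM), each the only set of its line with counts, and the 24-day vGlut2 set in Calca (382.7 CPM). The line label of the 26-day set may be wrong, which was not tested, and values of the vGlut2 line over 4 sets rest on it. Without this set Gad1 differed between the reporter lines by 9.30 in place of 5.48, and the oligodendrocyte median against wild type was -5.07 in place of -1.92.

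In wild type, excitatory cells stood apart for Gad2 in the 19-day set (27.8 CPM), Gad1 in the 21-day set (85.6 CPM), Gm5 in the 26-day set (6.53 CPM) and Grpr in the 22-day set labelled female (106.5 CPM). Inhibitory cells stood apart for Tac2 in the 19-day set (133.75 CPM), Nmur2 in the set labelled female (3.54 CPM), Rprm in the 20-day set (2.85 CPM), Nell1 in the 27-day set (8.52 CPM) and Grpr in the 21-day set (11.3 CPM). Against the vGat line, wild-type values stood apart for Akap5 in the 18-day set (43.9 CPM) and for Hapln2 (244.1 CPM), Hbb-bs (442.3 CPM) and Anln (237.05 CPM) in the set labelled female. Against the vGlut2 line they did so for Tac2 in the 28-day set (1775 CPM) and Gab1 in the 22-day set labelled male (123 CPM).

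The class difference in the reporter lines differed from that in wild type in 22 genes, by an interaction term. It used only reporter cells whose class matches their line, and the animal set was not a block. Named genes among them were Slc17a6 (-6.44), Cacna2d1 (-6.13), Adcyap1 (-5.17), Gm14204 (6.69), Gad2 (3.16), Sall3 (3.64), Mia (-4.88), Nmu (-8.47) and Nr2f2 (6.21). In single cells, 5 cells of the vGlut2 line with inhibitory type labels, all of the 26-day set, held Gad1 at 396.1 CPM (20 UMIs, exact Poisson interval 241.9 to 611.7). They held 0 Slc17a6 UMIs (upper limit of the exact Poisson interval 73.1 CPM). These cells are part of the reporter line comparison, which took all cells of each line.

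Other splits of the animal sets tested whether chance could give as many genes. For the reporter lines the real split alone gave as many genes (1 of 35 splits, 938 real, highest other 835). That is the smallest share 35 splits allow, and another split came close, so chance is not excluded. The split with 835 puts the 26-day vGlut2 set with vGat sets, which points to a structure of the samples. Chance is argued against for the vGat line (1 of 100, 1630 real, highest other 2) and the vGlut2 line (1 of 100, 1081 real, highest other 0). Classes and neuron types were assigned from the expression of the same cells, which fixes the outcome, so their splits say nothing about chance. The values were 1 of 64 for the classes (458 real, highest other 21) and 1 of 21 each for excitatory and inhibitory neuron types (12.9% and 16.85% of gene and type pairs real, highest others 0.952% and 0.916%). For age, 11 of 100 splits in inhibitory cells (3 real, highest other 9) and 24 of 100 in excitatory cells (2 real, highest other 30) gave as many genes, so chance cannot be excluded. What sets the split with 30 apart was not tested. The conflicting type was assigned in this way too, and its 16 splits are too few for a share under 0.05 (1 of 16 each; 1.19% and 4.303% of genes real, highest others 0.139% and 0.937%).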

How the results depend on the processing

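The tests with the Xist share, with types weighted by their cells and with the 22-day sets summed were chosen only after the result was seen. The genes picked by fixed rules kept direction and call under the alternatives in 100% of values for the classes (24 genes), 98.5% for the reporter lines (24), 99.1% for the vGat line and 98.8% for the vGlut2 line (20 each), 88.6% for neuron types, 34 of 41 and 25 of 32 for age, 94.4% for the conflicting type and 91.2% for type shares. The naming rule took large, consistent differences, which favours kept calls. Several list genes outside these percentages lost theirs, as given in the report. Fits of the conflicting type (14 cells) recovered 7% (against excitatory) and 5% (against inhibitory cells) of simulated 2-fold changes. For all changes below the cause was not tested, except that alternatives with fewer sets or cells hold fewer data. Percentages are of the genes, or gene and type pairs, tested in the report's own setting, also for alternatives.

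For the reporter lines, a filter of 20 CPM gave 2.77% of genes higher (3.95% of the 7441 tested there), limma on single-cell means 1.55% higher and 1.12% lower, age as a covariate 1.755% and 1.36%, and capture runs as units 8.21% and 7.86% (10.9% and 10.4% of the 7998 genes tested there). Leaving out a set gave 1.88 to 7.02% higher and 1.99 to 6.92% lower. For the classes, the fit with no replicate block gave 1.66% higher and 1.303% lower (2.19% and 1.72% of the 6170 tested there), at least 20 cells 1.93% higher and no filter 3.97% lower (1.79% of 18072). With each set left out in turn the values were 2.35 to 2.99% and 1.87 to 2.69%. For the vGat line, no filter gave 12.92% higher (5.39% of the 18439 tested there), limma on single-cell means 2.51% and 5.62%, runs 3.15% and 4.49% (of only 1824 genes tested there 13.3% and 18.9%, a higher share than in the report), limma with types weighted by their cells 3.63% and 6.53% and with types weighted equally 1.57% and 4.45%, and the Xist share 4.24% higher. Leaving out a set gave 3.27 to 8.30% and 9.64 to 14.2%. For the vGlut2 line, no composition factors gave 6.69% higher, limma on single-cell means 2.304% and 7.01%, limma with types weighted equally 1.59% and 5.85%, and runs 5.98% lower (17.2% of the 2484 tested there, also a higher share). With each set left out in turn the values were 1.68 to 6.09% and 4.05 to 12.6%.

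For age in inhibitory cells, DESeq2 gave 1 gene higher, no filter 6 higher and 5 lower, and 0 were lower with 20 CPM, limma on single-cell means or the set labelled female. Leaving out a set gave 1 to 4 and 0 to 2. For age in excitatory cells, DESeq2 gave 3 higher and 6 lower, no filter 12 and 9, and 0 were lower with limma on single-cell means, the set labelled female or the Xist share. With each set left out in turn the values were 1 to 3 and 0 to 4. For excitatory types, reporter cells only gave 2.35% higher and 0.918% lower, at least 3 cells 2.01% lower, no replicate block 2.07% lower and wild-type cells only 1.46% lower, and for inhibitory types wild-type cells only gave 4.24% and 1.65%. Npy in Glut4 reversed with wild-type cells only, to -2.04. With an estimated correlation, lists called went from 8 to 4 (reporter lines), 12 to 4 (classes), 5 to 2 (vGat line), 7 to 1 (vGlut2 line), 5 to 0 and 4 to 0 (age).

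For the conflicting type against excitatory cells, all sets with at least 1 cell gave 0.558% lower (2 list genes lower), no replicate block 0.401% higher and DESeq2 0.244% higher and 0.262% lower. Leaving out a set gave 0.0523 to 0.105% higher, 0.401 to 1.90% lower, and 2 to 3 and 3 to 5 list genes. Against inhibitory cells, all sets gave 0.0347% higher and 0.972% lower, no replicate block 3.96% higher and DESeq2 1.42% lower. With each set left out in turn the values were 0.278 to 3.33%, 1.11 to 4.58%, and 0 to 0 and 5 to 6 list genes.

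With at least 20 cells per set 0 excitatory type shares were called, but 2 vGlut2 sets allow no p under 0.0222 there, and the differences were 14.5 (Glut6) and 16.01 (Glut7) in place of 11.3 and 10.5. Leaving out a set gave 0 to 3 excitatory and 0 to 0 inhibitory calls. Differences in share that reversed, none of them called, are in percentage points. With at least 20 cells they were 4.76 (Gaba3), 1.02 (Gaba5) and -0.717 (Glut1). Leaving out a set gave -1.99 to 0.134 for Gaba14, -2.87 to 3.27 for Gaba3, -0.800 to 0.275 for Gaba4, -1.06 to 0.691 for Gaba5, -1.16 to 0.736 for Glut2, -2.59 to 0.918 for Glut4 and -1.33 to 2.47 for Glut8.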

Other observations

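No test in this part was chosen after the result was seen. Its values belong to the fixed rules for neuron types, except the counts of the 1 vGat cell given last. In excitatory types, Nmb was higher in Glut12, a type named for Qrfpr (log2 difference 2.94, SE 0.58; 81.4 ± 160 against 11.6 CPM; 8 sets), Qrfpr itself in Glut11 (2.73, SE 0.50; 95.5 ± 104.3 against 24.3 CPM), and the peptide gene Calca in Glut5 (2.71, SE 0.48; 430 ± 288.25 against 116.1 CPM). In inhibitory types, Nppc was higher in Gaba9 (1.302, SE 0.27; 224.01 ± 58.4 against 86.8 CPM), Cckbr in Gaba12 (2.31, SE 0.48; 37.8 ± 18.7 against 10.8 CPM), and Trhr in Gaba7 (2.42, SE 0.47; 66.4 ± 51.98 against 30.7 CPM). The 1 vGat cell annotated to an excitatory type, Glut15, held 7 Gad1 UMIs and 0 Slc17a6 UMIs.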
